A study of Canis lupus familiaris with 20 samples.

How the data were processed

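Snap-frozen tumour tissue of 10 dogs gave 10 primary insulinomas, 7 lymph node metastases and 3 liver metastases, 1 metastasis for each dog. Per the labels' protocols, total RNA was amplified to cRNA and coupled to Cy3 or Cy5, and the sample was hybridised on a spotted array together with a reference pool of equal amounts of cRNA from all 20 samples. Per the labels, both samples of dogs 11, 13, 15, 17 and 19 carried Cy5 and both samples of dogs 9, 14, 16, 20 and 21 carried Cy3, with the pool in the other dye.

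The deposited spot tables give, per the file headers, the mean intensity of each spot and of its local background in Cy3 and Cy5, quality flags and saturation flags. The scanner and image software are not given in the sources used here. The deposited spot tables and the series table also hold log2 ratios of Cy5 to Cy3 that the authors normalised by print-tip, per the file headers, and that are not turned for the dye. Each column of the series table equalled the spot tables within 2.2e-05. The medians of its 20 columns lay between -0.03 and 0.01, and it was used as an alternative.

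Each array had 22176 spots in 48 print blocks. Of these, 20313 held clones and 1863 were controls or empty and were left out after the background correction. There were 20160 different clones, 55 of them spotted more than once and averaged. Backgrounds were corrected by normexp with an offset of 50 and each array was normalised by global loess, with clone spots weighted. Spots marked by the authors were left out, which removed 2629 clone spots in the primary tumour of dog 21 and at most 220 on any other array. No spot was saturated. A spot counted as above background when its signal exceeded the local background by more than 2 standard deviations of that background. Ratios of arrays with the sample in Cy3 were turned, so that each value is log2 of sample over pool.

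The direction was checked by the make-up of the pool. A sample that is 1 of 20 equal parts of the pool can exceed it at most 20-fold, a log2 ratio of 4.32, while nothing bounds the ratio below. After turning, 0 clones exceeded 4.32 on any array in the values used here, whose offset of 50 shrinks the ratios of dim spots, and 19 of the 20 arrays had clones further below the pool than that. In the authors' values the highest ratio was above the bound on 20 of 20 arrays, from 4.35 to 12.7. A further check, added after the data had been seen, took the authors' values of spots whose denominator exceeded the median signal of its channel on the array. There the bound was exceeded on 1 array, by 3 spots, with the ratios as turned, and on 19 arrays with the ratios turned the other way. The lowest correlation between arrays of 1 dye was -0.0792. The deposited summaries of spot counts matched the spot table of their own sample for 8 samples and that of another sample for 12 samples of 6 dogs, with at most 3 spots of difference. The tables, not the summaries, were used. For 8 of the 12, the other sample had the other dye. The 8 tables those summaries came from exceeded the bound if turned the other way, 8 of 8 in the values used here and 8 of 8 in the authors' values of such brighter spots, which speaks against moving these tables to the dogs of the summaries. The summaries of dog 14 came from the tables of dog 9 and those of dog 19 from the tables of dog 17, dogs of the same dye, and this check says nothing on them. Dogs 14 and 19 are 2 of the 3 dogs with a liver metastasis, and dogs 9, 17 and 19 have intervals while dog 14 has none, so the lymph node, liver, site and interval results depend on these tables being attached to the right dogs.

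Between dogs the dye and the dog go together. A limma fit over all arrays had no term for the dog, so both arrays of a dog counted as independent. In it 9208 clones, 45.7%, differed between the Cy5 and the Cy3 dogs at an adjusted p under 0.05. Comparisons were therefore made within dogs, where the dye cancels, or with the dye as a term. The series design describes each metastasis as accompanying a primary tumour, and the dog label ties both samples, so the dog was kept as a fixed block in the main fit. After subtracting the group means within each dye, samples of 1 dog correlated at 0.0300 to 0.570. In 7 of 10 dogs the primary tumour correlated best with the metastasis of its own dog, among the metastases of the same dye. With each dye centred without regard to the groups, 8 of 20 arrays correlated best with the other array of their dog, among arrays of the same dye. The fit without the block was run as an alternative.

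Tests across clones used limma 3.58.1 in R 4.3.3 (lmFit and eBayes) with Benjamini-Hochberg adjustment, two-sided, at an adjusted p of 0.05. The metastasis comparison had 1 term, and the lymph node, liver and interaction results came from a fit with both sites as terms and a shared spread. The interval was fitted as log2 of days plus 1 with the dye as a term in 9 primary tumours, since dog 14 had no surgery. The script was tested on simulated data with the measured spread of each clone's within-dog differences. It recovered 96.5% of 200 clones changed by 1 on the log2 scale for metastases against primary tumours, 93.5% for lymph node, 79.0% for liver and 75.5% for the difference between sites. For the interval it recovered 73.5% of clones changed by 1 over the whole range of intervals. For changes of 0.5 the shares were 80.0%, 72.0%, 44.5%, 36.0% and 25.5% in that order. The simulated clones varied independently, while the real clones co-varied, and clones of every size were changed together. For the interval too the spread was taken from the within-dog differences, not from the spread between primary tumours. The shares therefore test the script and are not the power of this design.

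The reference table used here lists genes of the dog, and 0 of the 20160 clone identifiers matched it. The 24 gene lists with 477 genes that were fixed before the data were examined, and every alternative of the list test, could not be run, and their results are not reported here. For the same reason the rule for named genes could not be followed. In its place up to 2 clones in each direction of a comparison, those with the smallest p, are given by identifier as values.

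Clone groups were added after the data had been seen. Clones measured on at least 19 arrays with a standard deviation of at least 1 over the arrays, after centring each dye, were clustered by average linkage on 1 minus Pearson's r. The tree was divided at a height of 0.4 and groups of at least 10 clones were kept. A first look used clones measured on every array, which is given as an alternative. Each group's level is the mean of its clones. Within-dog differences were tested by exact sign-flip tests, differences between sites by the exact test of all divisions of the 10 dogs into 7 and 3, and correlations by exact permutation of 9 dogs, in Python 3.11.15 with scipy 1.17.1, numpy 2.4.6 and pandas 2.3.3, and figures with matplotlib 3.10.9. The count of clones moved at least 2-fold in at least 5 dogs was set against all sign flips of the dogs.

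The alternatives fixed before the data were examined were the authors' values, no background correction, median centring, scaling between arrays, leaving out the dimmest clones, no dog block, array series as a term, dogs of 1 dye alone, array weights, each dog left out in turn, an adjusted p of 0.1, and for the interval survival time, ranks and no dye term. The array series is the leading part of the array number, with 9, 8 and 3 arrays in series A, B and C. Alternatives for the clone groups and for flagged spots were chosen after the data had been seen.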

Results

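Canine insulinoma is a tumour of the insulin-secreting beta cells of the pancreas. Expression was profiled in the primary tumour and 1 metastasis of 10 dogs, 20 samples in all, and the metastasis came from a lymph node in 7 dogs and from the liver in 3 dogs. Each sample was hybridised with a pool made from all 20 samples, so every level is a log2 ratio of the sample to that pool. The arrays carried 20160 different clones. The share of clone spots above background in the sample channel ran from 87.3% in the liver metastasis of dog 19 to 98.6% in the lymph node metastasis of dog 16. The clone identifiers are not paired with gene names in the material used here, so the results are given for clones and for groups of clones that varied together. There is 1 array per sample, and the number of dogs limits the precision.

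The main question of the design was how a metastasis differs from the primary tumour it came with. Within single dogs the differences were wide and ran both ways. The liver metastasis of dog 15 had 660 clones at least 2-fold higher and 418 at least 2-fold lower than its primary tumour. The lymph node metastasis of dog 13 had 280 clones higher and 473 lower by that measure, and that of dog 20 had 400 higher and 319 lower. By contrast, the lymph node metastasis of dog 21 had 35 clones higher and 39 lower, and the liver metastasis of dog 19 had 34 higher and 41 lower. The median over the 10 dogs was 132 clones higher and 291 lower, and with the authors' values 312.5 higher and 445.5 lower. These are values of single pairs with no replicate array.

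**Figure D1:**
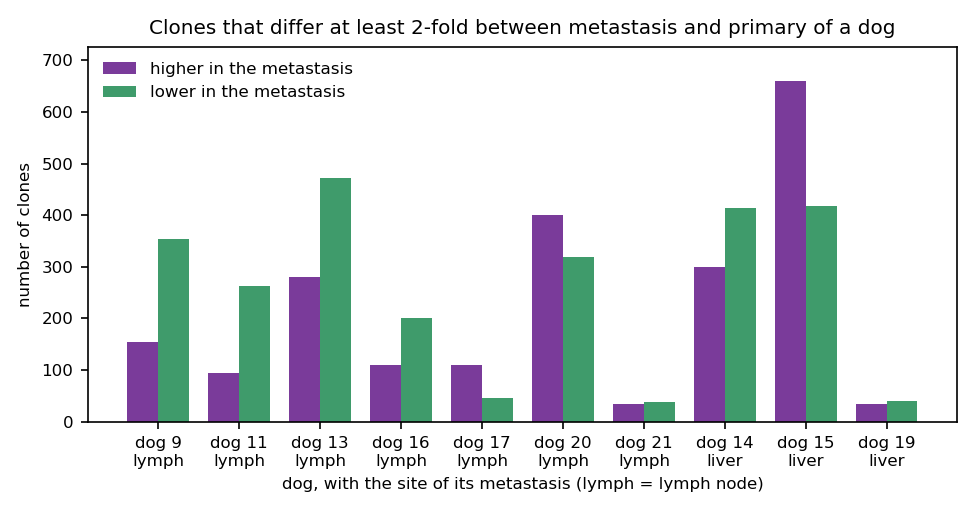
Number of clones (vertical axis) at least 2-fold higher (purple) or at least 2-fold lower (green) in the metastasis than in the primary tumour of each dog (horizontal axis, 7 dogs with a lymph node metastasis and then 3 with a liver metastasis). Dog 15 had the tallest bar, 660 clones higher, and dogs 19 and 21 stayed under 50 clones in both directions.

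In at least 1 dog, 1614 clones were at least 2-fold higher in the metastasis and 1450 at least 2-fold lower, and 444 clones were both, in different dogs. A level at least 2-fold lower in the metastasis of at least 5 dogs was found for 139 clones, and at least 2-fold higher for 8 clones. With the authors' values the counts were 217 lower and 58 higher. The sign of whole dogs was turned in all 1024 ways. Of these, 64 gave 139 or more clones in either direction (exact two-sided sign-flip p = 0.0625). The test cannot decide whether the count exceeds what the spread between dogs gives, since the limit of 5 dogs largely set its p. In at least 6 dogs, 9 clones were at least 2-fold lower and 2 higher. Most of the 139 therefore met the limit in exactly 5 dogs. Of the 139 clones, 49 belonged to the second clone group described further on. The median correlation of the 139 with that group's mean was 0.98. That group fell most in dogs 9, 11, 13, 16 and 20, so turning only the other dogs leaves most of these clones counted.

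Across all 10 dogs, no clone passed an adjusted p of 0.05 in the limma fit of metastases against primary tumours with the dog as a block. The smallest adjusted p was 0.696. At an unadjusted p under 0.05 there were 1323 clones, 6.56% of those tested against the 5% that chance gives, 416 of them higher and 907 lower in metastases. The clones with the smallest p are given as values. The leading clone among those higher in metastases differed by 0.17 ± 0.03 (log2, SE) and was higher in 10 of 10 dogs, and DG11-170l24 differed by 0.28 ± 0.06 and was higher in 8 of 10 dogs. DG9-264n23 differed by -0.59 ± 0.10 and was lower in 8 of the 9 dogs measured, and DG8-102m8 differed by -0.25 ± 0.05 and was lower in 10 of 10 dogs. Each had an adjusted p of 0.696 in limma. For 97.7% of the clones, the 95% confidence interval of the mean difference lay within 2-fold in both directions.

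To describe what varied most, clones were grouped by how they co-varied over the 20 arrays, with no use of the tumour groups. This was decided after the data had been seen. Of 19958 clones, 227 had a standard deviation of at least 1 on the log2 scale, and 165 of them fell into 5 groups of 60, 50, 25, 15 and 15 clones. Several clones can stand for 1 transcript, so the number of clones is not a number of genes. The first group had its highest level in a single sample, the liver metastasis of dog 15, at 3.57 on the log2 scale, while the other 19 samples lay between -2.35 and -0.08. A transcript present in 1 of the 20 pooled samples alone could reach 4.32. The third group was highest in the lymph node metastasis of dog 9, at 2.30, against -2.03 in its primary tumour. The fourth group was lowest in the liver metastasis of dog 15, at -3.27, and in the lymph node metastasis of dog 9, at -2.61. The fifth group was highest in the liver metastasis of dog 15, at 2.51, and in the primary tumour of dog 17, at 2.02.

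The second group, of 50 clones, differed most between primary tumours and metastases. Its mean level in the primary tumours was 2.03 in dog 13, 1.65 in dog 20, 1.40 in dog 9, 1.27 in dog 11 and 0.63 in dog 16. It was -1.57 in dog 21, -1.79 in dog 17, -2.23 in dog 19, -2.26 in dog 15 and -2.49 in dog 14. All 10 metastases lay between -2.51 and -0.32. The metastasis had the lower level in 7 of 10 dogs, with a mean difference of -1.48 ± 1.92 (log2, SD, n = 10), from -4.14 in dog 13 to 1.48 in dog 17. The exact two-sided sign-flip test gave p = 0.0391 and an adjusted p of 0.195 over the 5 groups, so the difference did not hold after correction. All 50 clones had a mean below 0, 48 of them at an unadjusted p under 0.05 in limma and 0 at an adjusted p under 0.05. The clones were grouped because they co-varied, each with a correlation of at least 0.85 with the group's mean. Their agreement follows from the grouping and adds no support to the group's difference.

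The difference of the second group was -1.30 in the 5 dogs labelled with Cy5 and -1.67 in the 5 dogs labelled with Cy3. The arrays came from 3 array series. In the 5 dogs whose arrays both came from 1 series the mean difference was -1.16 (exact p = 0.375, where 5 dogs allow no p under 0.0625). With series as a further term it was -1.36 (exact p = 0.141). After centring each dye, the metastases of a series were also set against its primary tumours, without pairing and in part across different dogs. The means differed by -2.39 in series A (6 primary tumours, 3 metastases), -0.75 in series B (3 and 5) and -0.14 in series C (1 and 2). Without dog 9, 11, 13, 16 or 20 the exact p was 0.0781 each time, and without dog 17 it was 0.0156 (adjusted p = 0.0781), with a mean difference of -1.81.

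For the other groups the mean within-dog difference was 0.61 ± 1.61 (SD, n = 10) in the first, 0.48 ± 1.58 in the third, -0.06 ± 1.62 in the fourth and 0.30 ± 1.08 in the fifth. None exceeded the spread between dogs, with exact sign-flip p from 0.309 to 0.912. Dog 15 held most of the first group's mean, since its difference was 4.91 and the mean without it was 0.13. Dog 9 held most of the third group's mean, with a difference of 4.34 and a mean of 0.05 without it. Dog 15 also held most of the fifth group's mean, with a difference of 2.54 and a mean of 0.050 without it.

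**Figure D2:**
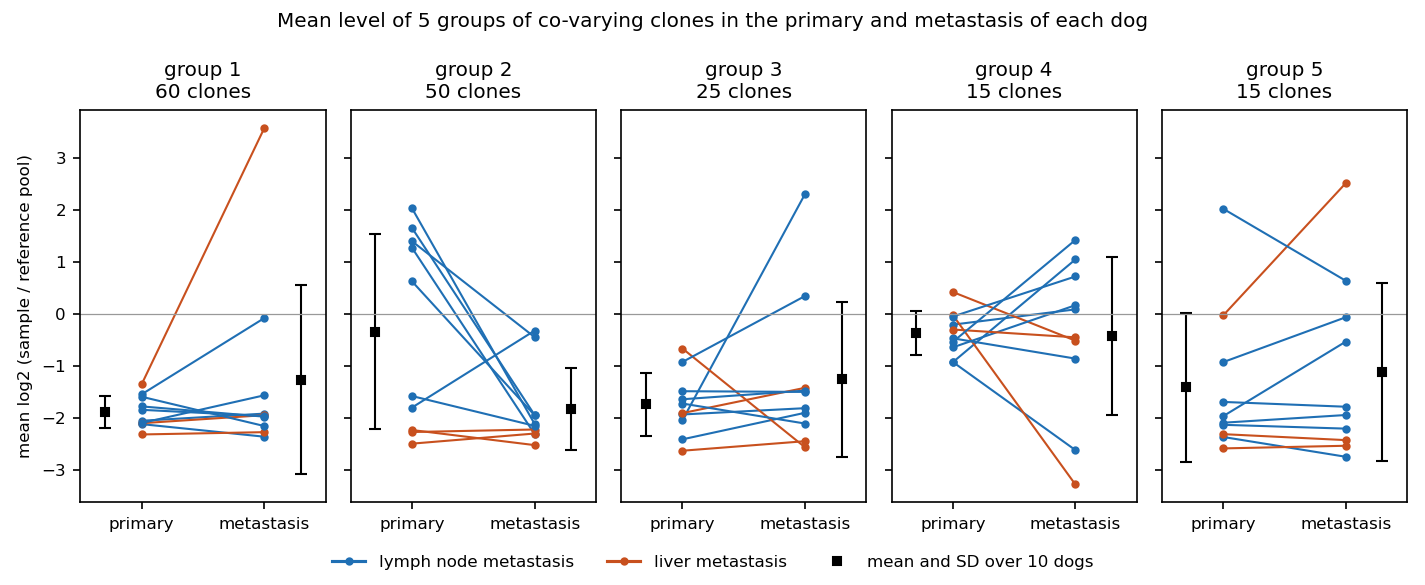
Mean log2 ratio of sample to reference pool (vertical axis) of the 5 clone groups in the primary tumour and the metastasis of each dog (points joined by a line, blue for lymph node and orange for liver metastases), with the mean and SD over 10 dogs as black squares and bars. In the second group the lines of dogs 9, 11, 13, 16 and 20 run from between 0.63 and 2.03 in the primary tumour to -0.44 or lower in the metastasis, and in the first group the line of dog 15 ends at 3.57.

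The labels give the site of each metastasis, so lymph node metastases were set against their primary tumours in 7 dogs. The mean of the second clone group differed by -2.11 ± 2.00 (SD, n = 7) and was lower in 6 of 7 dogs (exact sign-flip p = 0.0469, adjusted p = 0.234 over the 5 groups). Without dog 9, 11, 13, 16 or 20 the exact p for the second group was 0.0938, and without dog 21 it was 0.0625. Without dog 17 the difference was -2.71 (exact p = 0.0313, adjusted p = 0.156). The exact p of the other groups ran from 0.156 to 0.875, and over all alternatives from 0.0313 to 0.984, with the lowest for the third group with scaling between arrays (adjusted p = 0.117 over the 5 groups). No clone passed an adjusted p of 0.05 in limma. An unadjusted p under 0.05 was found for 1654 clones, 8.20% of those tested, with 556 higher and 1098 lower in lymph node metastases. A mean at least 2-fold lower was estimated for 138 clones and at least 2-fold higher for 14. The smallest adjusted p, 0.102, belonged to DG9-34n17, at -0.50 ± 0.06 (log2, SE) and lower in 7 of 7 dogs. This count depended on dog 17, whose metastasis had the higher level of the second group. Without dog 17, 215 clones passed, 208 lower and 7 higher in lymph node metastases, and 45 of them were clones of the second group.

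The spot-count summaries of dogs 14 and 19 came from tables of dogs 9 and 17, of the same dye. The lymph node, liver, site and interval results therefore depend on these tables being attached correctly. The bound of the pool could not check the tables of dogs 9 and 17. It spoke against moving the tables of dogs 14 and 19 to the dogs whose summaries came from them. In the 3 dogs with a liver metastasis, the mean of the first clone group was higher than in the primary tumour by 4.91 in dog 15, 0.15 in dog 14 and 0.04 in dog 19. The fourth group was lower in 3 of 3 dogs, by differences of -3.25 in dog 15, -0.93 in dog 14 and -0.15 in dog 19, and the exact p could not go below 0.25. The second group differed by -0.29, 0.05 and 0.19 in dogs 19, 15 and 14. No clone passed an adjusted p of 0.05 in limma for liver metastases against primary tumours, and 1588 clones had an unadjusted p under 0.05, 834 higher and 754 lower. The smallest adjusted p was 0.117, for DG42-137o12, which was higher by 1.08 ± 0.13 (log2, SE) in 3 of 3 dogs. Without dog 14, 2 clones passed, DG10-1b10 at 3.58 ± 0.20 and DG32-42l19 at 1.57 ± 0.12. Without dog 19, 5 clones passed, 2 higher and 3 lower. Among these, DG8-83i17 was at 0.92, DG11-249k20 at 0.82, DG2-120o6 at -1.04 and DG2-109j5 at -1.13. These 6 clones are named after their values were seen.

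The difference between the sites was tested as an interaction. No clone passed an adjusted p of 0.05 in limma, the smallest being 0.371, and 1720 clones had an unadjusted p under 0.05, 8.53% of those tested. Without dog 14, DG10-1b10 and DG32-42l19 passed here too. Of the clone groups, the fourth had a difference from the primary tumour lower in liver than in lymph node metastases by -1.98 (exact p = 0.075, adjusted p = 0.222 over the 5 groups). Without dog 9 this was -2.35 (exact p = 0.0238, adjusted p = 0.119), and with the median over the clones in place of the mean it was -2.03 (exact p = 0.0417, adjusted p = 0.208). Without dog 15 it was -1.07 (exact p = 0.333). The second group's difference lay 2.10 higher in liver than in lymph node metastases (exact p = 0.117). Without dog 17 it lay 2.70 higher (exact p = 0.0238, adjusted p = 0.119). The primary tumours of the liver dogs were already at -2.49 to -2.23, near their metastases at -2.51 to -2.21. All primary tumours above 0, those of dogs 9, 11, 13, 16 and 20, belonged to lymph node dogs. This contrast therefore cannot tell a difference between the sites from one between the primary tumours. The other groups had an exact p from 0.133 to 0.367. With 7 dogs against 3 the smallest p is 0.00833.

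The labels give a disease-free interval for 9 dogs, from 0 to 1565 days, and the longest is a lower bound because that dog was free of disease at the end. Among primary tumours, no clone was associated with the interval at an adjusted p of 0.05 in limma, and 383 clones, 1.90% of those tested, had an unadjusted p under 0.05. The levels of the 9 primary tumours were centred on the mean of all arrays of a dye, metastases included. An extreme metastasis therefore shifts the primary tumours of its dye. Without centring, Pearson's r of the clone groups with the log2 interval ran from -0.521 in the third group to 0.198 in the second. In the first group it was -0.393. With centring, r ran from -0.545 in the first group to 0.236 in the second. The exact permutation p of Pearson's r ran from 0.131 to 0.583, and the adjusted p over the 5 groups was at least 0.412. Spearman's rho ran from -0.611 in the third group to 0.410 in the second, with an exact permutation p of at least 0.0878. For the third group r was -0.503 (exact permutation p = 0.165). It was -0.222 without dogs 15 and 20, whose intervals of 0 days are farthest from the median on the log2 scale. Without dog 17 it was -0.774 (exact permutation p = 0.00898, adjusted p = 0.0449 over the 5 groups). The tables of dog 17, like those of dog 9, could not be checked by the bound of the pool. The dyes held 5 and 4 of these dogs, fewer than the 6 required here for a correlation, so none is given within a dye. With survival time in place of the interval, r ran from -0.535 to 0.217, with an exact permutation p of at least 0.115. Of the survival times, 2 are lower bounds, and those of dogs 15 and 20 are 0 and 1 days.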

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

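The tests of a shared property of liver metastases, of host tissue, of array series, of non-tumour tissue and of dye bias were chosen only after the result was seen. Whether a sample stood apart was tested in 21 sets of values, of which chance marks about 1 in 20. This share does not hold for the clone groups, which were formed from co-variation. That favours groups with 1 extreme sample.

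The first clone group stood apart in dog 15, where the liver metastasis was 4.91 above the primary tumour and the next dog was at 1.46. The primary tumour of dog 15 was in array series A and its metastasis in series C. With series as a term the group's mean difference was 0.010, but no other dog went from A to C, so the term takes up this dog's difference. Both arrays of dog 19 were also in series C, at -2.31 and -2.27, so the group was not high throughout that series. The higher of the other 2 liver differences was 0.154, so the mean of this group was not raised alike in the 3 liver metastases. Since the grouping favours clones with 1 extreme sample, this cannot decide whether other clones share a property of liver metastases. A local defect of the array is argued against, since the print block with most of the group's clones held 6.67% of them. Tissue of the host organ in that specimen stays open, although the design text says that fragments came from the centre of the tumour. It cannot be told apart from a change in the tumour cells, because 0 clones have a gene name to test markers with. The biological difference between dogs was not tested.

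The first group also stood apart in the lymph node metastasis of dog 13, at -0.076 (log2 ratio to the pool) against -1.56 for the next of the 7 lymph node metastases. The third group stood apart in dog 9, with a within-dog difference of 4.34 against 1.27 in the next dog. In dogs 13 and 9 the primary tumour was in array series A and the metastasis in series B. In the primary tumour of dog 21, 2629 clone spots were marked by the authors, against 170 in the next primary tumour. In the primary tumour of dog 13, 94.1% of clone spots were above background, against 97.0% in the next lowest primary tumour.

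The second clone group was lower in the metastases of some dogs, by -4.14 in dog 13, -3.59 in dog 20, -3.57 in dog 11, -2.57 in dog 16 and -1.84 in dog 9. Saturated spots are argued against, since none was saturated. At least 98.0% of the group's clones were above background in every primary tumour. Over all clone spots that share ran from 94.1% in the primary tumour of dog 13 to 98.6% in that of dog 9. The group's share is near it and so says little against dim spots. With array series as a term the mean difference was -1.36 (exact p = 0.141), which does not exceed the spread between dogs, so that fit cannot decide. In dogs 11 and 20 both arrays came from 1 series, so a difference between series cannot give their falls. This argues against array series for these dogs. In dogs 9, 13 and 16 the primary tumour was in series A and the metastasis in series B. There array series stays open and cannot be told apart from a difference between the tumours. The 5 dogs with both arrays in 1 series went both ways, at -3.59 in dog 20, -3.57 in dog 11, -0.29 in dog 19, 0.19 in dog 14 and 1.48 in dog 17. The primary tumours of dogs 19, 14 and 17 were already low, at -2.23, -2.49 and -1.79, against 1.65 and 1.27 in dogs 20 and 11. Non-tumour tissue in the primary specimens stays open and cannot be told apart from a difference between the tumour cells, since 0 clones have a gene name to test markers with. Chance over the dogs is not excluded after correction over the 5 groups.

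Clones differed widely between the Cy5 and the Cy3 dogs. The correlation over clones of the mean Cy5 to Cy3 ratio between both sets of dogs, 0.0636, was meant to tell a dye bias from a difference between the dogs. The test is void, because a reference pool that holds both sets makes a true difference between the sets give a positive correlation as well. Dye bias and a difference between the dogs cannot be told apart, since each dog was labelled with 1 dye.

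The number of clones at an unadjusted p under 0.05 was set against other sign patterns or divisions of the dogs. For metastases against primary tumours, 18 of 100 patterns gave at least the real 1323 clones and the highest other gave 1995, so chance is not excluded. For lymph node metastases 5 of all 64 patterns gave at least the real 1654 and the highest other gave 1965, and chance is not excluded. For the difference between sites 12 of 100 divisions gave at least the real 1720 and the highest other gave 2620, and chance is not excluded. For liver metastases the 4 possible patterns are too few for a share under 0.05. The real count was 1588, 3 of the 4 patterns gave at least that many, and the highest other was 1912.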

How the results depend on the processing

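Alternatives for the clone groups, the 2-fold counts and marked spots were chosen after seeing the data. No clone passed in any of 23 settings, the main one included, for metastases against primary tumours, where 774 to 1647 clones had an unadjusted p under 0.05, nor in any of 20 for the interval (121 to 880 clones). For lymph node, liver and site results the count was 0 except where dogs were left out, where it ran from 0 to 215, 0 to 5 and 0 to 2. Without the dog block and pairing, limma gave 0 clones in each of the 4 comparisons, with 946, 625, 1538 and 1240 at an unadjusted p under 0.05, and the second group's p was 0.0367, so the block changed no call. Of 566 alternatives of these and the group results, 509 kept direction and side of the threshold, by unadjusted p for the groups, or stayed within 1.5 times. Of the others 18 turned direction, 18 moved by more than 1.5 times, 15 lost and 6 gained a p under 0.05. All 15 that lost it were of the second group, over all dogs or in lymph node dogs, since no other group result had such a p. Most alternatives started from a count of 0 or a p above 0.05, so the 509 are no measure of robustness. After adjustment over the groups of a setting, 1 of 401 group alternatives was under 0.05, the third group's correlation with the interval without dog 17.

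With the authors' values the clones at least 2-fold lower in at least 5 dogs were 217 and those higher 58, and the medians over dogs were 445.5 lower and 312.5 higher. The cause was not tested. Leaving out each dog gave 9 to 139 lower and 2 to 7 higher with the limit kept at 5 dogs. Only 9 clones were lower in at least 6 dogs, so the low end follows from the limit and is no test.

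The second group's mean difference ran from -1.81 to -1.19 without each dog and was -1.30 in Cy5 dogs, -1.67 in Cy3 dogs, -1.36 with series as a term and -1.16 in dogs of 1 series. Sets of 5 dogs cannot reach a p under 0.0625. In dogs of 1 series, the first group turned to -0.16, the fourth to 0.16 and the fifth to -0.32. The fourth group's mean of -0.06 also turned with scaling (0.053), in Cy3 dogs (0.18) and with series as a term (0.31), and ran from -0.29 to 0.29 without each dog. None of these turned means had an exact p under 0.05.

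In lymph node dogs, leaving out each dog gave -0.075 to 0.26 for the first group, -2.71 to -1.78 for the second, 0.28 to 1.06 for the third, 0.29 to 0.90 for the fourth and -0.15 to 0.32 for the fifth, which turned to -0.012 with median centring and -0.0065 with a standard deviation limit of 0.7. The third group was at 1.06 with scaling (exact p = 0.0313, adjusted p = 0.117) and at 0.28 without dog 9 (exact p = 0.313). Scaling also moved the first group to 0.43 (exact p = 0.219) and the fifth to 0.37 (exact p = 0.344). For the site difference the ranges were -0.045 to 2.39, 1.76 to 2.70, -1.71 to -0.52, -2.62 to -1.07 and -0.11 to 1.22 in groups 1 to 5, with -0.045, -0.52, -1.07 and -0.11 in groups 1, 3, 4 and 5 without dog 15, and the fourth group was at -2.03 with the median over clones. For Pearson's r with the interval they were -0.632 to -0.353, -0.00093 to 0.534, -0.774 to -0.212, -0.415 to 0.106 and -0.667 to -0.0829 in groups 1 to 5, and the third was -0.643 with the median over clones (exact permutation p = 0.0430, adjusted p = 0.215). The cause was not tested. The list test was not run for want of gene names. Signal limits the ratios of dim spots, since the offset shrinks them, and 87.3% of clone spots were above background on the weakest array.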

Other observations

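The first part of a clone identifier, which names no gene, was unevenly spread over the clone groups. The 19958 clones considered for grouping were compared. Of the 11 whose whole first part is DG1, 8 were in the second group (Fisher's exact test, one-sided, p = 1.41e-19, adjusted p = 1.41e-18 over 10 tests). In each pair tested the group held at least 5 clones of that first part, and the adjustment does not cover a choice of pairs by such counts. The first group held 27 clones with DG32, 45.0% of its clones against 6.02% of those compared, 16 with DG42 and 5 of the 17 with DG10. The fifth group held 7 clones with DG32 and 6 with DG42, and the fourth group 9 with DG2 among its 15. Clones are not independent, since several can stand for 1 transcript, so these p-values are too small. The clones compared include those below the standard deviation limit, so a tie of the first part with spread alone would also lower the p-values.

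The levels of the first and the fifth group correlated over the 20 arrays at 0.601 after centring each dye, and both were highest in the liver metastasis of dog 15. In that sample 57 of the 60 clones of the first group were at a log2 ratio of at least 3. Of the 139 clones at least 2-fold lower in at least 5 dogs, 138 had a correlation over 0.5 with the second group's mean, and 90 lay outside the 5 groups. Of the 208 clones lower in lymph node metastases without dog 17, 207 did. Both sets were picked for lower levels in metastases, as the second group has, and include clones of that group. The selection therefore favoured these correlations.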
